A study of Mus musculus with 12 samples.

How the data were processed

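The data were RNA-seq libraries of Cd11b-positive brain myeloid cells from male mice of 6 months of age, 6 with a P301S human tau transgene and 6 without. Per the labels' protocols, cells were pelleted after sorting and RNA was extracted with a column kit for small samples. Per the submitters' processing notes, GSNAP and the mouse genome build GRCm38 were used. The version of GSNAP, the counting tool, the gene annotation release and the strandedness of the libraries are not given in the sources used here. Each library had 1 deposited table. Its count column holds, per the file headers, the number of uniquely aligned reads of each gene model, named by Entrez gene number. Its second column holds RPKM values that the authors adjusted by a size factor for each sample, per the file headers. In all 12 tables the adjusted RPKM equalled the count times a constant of the library and a constant of the gene, with a largest relative deviation of 2.1e-14, so both columns carry the same measurement. Because only unique reads were counted, genes with near-identical copies (histocompatibility genes, interferon-inducible clusters, ribosomal protein genes with pseudogenes) can be undercounted.

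The tables list 36528 gene numbers, of which 7220 had no count in any library. Symbols, gene types and coordinates (1-based) came from a RefSeq gene table of assembly GRCm38.p6, the same build, matched on the gene number. A match was found for 31049 numbers (85.0%), and the numbers without a symbol took between 1.56% and 3.15% of the counts of a library. They were kept in library sizes and tests. Groups were taken from the genotype label, and replicates were numbered within a group in the order of the sample records, so the number pairs nothing. All 30 pairs of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 18.2, over genes with at least 20 counts in the pair), so none was merged as a repeat of the same library. That each is a separate sample rests on its own sample identifier in the labels. Depth was 1196069 to 4145069 counts per library. The biological coefficient of variation of the tested genes was 0.64, so the spread between libraries, more than counting error, limited the precision of all but the lowest genes. Reads were counted without molecular identifiers, so counting intervals cover counting error only.

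Genes were kept by filterByExpr of edgeR with its default minimum count of 10, which left 10022. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust option, no covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are P301S minus NonTg, and each standard error is the fold change divided by the square root of its F statistic. CPM use TMM-scaled library sizes and are given as mean ± SD of 6 libraries. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation. The mean log2 CPM of each list per library was compared by a two-sided exact permutation test over the 924 assignments of 12 libraries to 2 groups of 6. Both families of p-values were adjusted over the 24 lists with at least 3 tested genes, and summed CPM over all 33 lists. Library measures were compared by the same exact test, adjusted over 9 measures.

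The 33 lists (691 entries, 687 matched) were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the first group of alternatives below. They covered homeostatic and disease-associated microglia, type I interferon, histocompatibility class I and II, proliferation, inflammatory cytokines and NF-kB, cholesterol synthesis, lipid handling, lysosome, complement, glycolysis, oxidative phosphorylation, the integrated stress response, Alzheimer disease risk orthologs, dissociation-induced immediate early genes and ribosomal proteins. The others held markers of border macrophages, monocytes, neutrophils, T cells, natural killer cells, B cells, dendritic cells, neurons, astrocytes, oligodendrocytes, their precursors, endothelium, mural cells, choroid plexus and ependyma, fibroblasts and erythroid cells. Only members kept by the count filter were tested, so counts of members called leave out the others. Tested were, for example, 9 of 30 proliferation, 11 of 24 cholesterol synthesis and 22 of 40 oxidative phosphorylation genes. The ribosomal protein list had 18 of 38 tested and the monocyte list 3 of 14. Named genes were the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 2 CPM, up to 4 members with the smallest p in each list described, and 11 genes always reported. The always reported genes were Mapt, Prnp, Itgam, Apoe, Trem2, Cst7, Itgax, Clec7a, P2ry12, Tmem119 and Cx3cr1. A few members that did not pass and are named beside a list were chosen after their values were seen. Results for 3 genes that were followed through the settings are not reported here.

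The gene test was tested on simulated counts with the NonTg means and the library sizes and dispersions of all 12 libraries, with 200 of 10022 genes changed. Of 50 genes changed at each size, it recovered 3 at 2-fold, 16 at 4-fold, 35 at 8-fold and 44 at 16-fold, with 3 false calls among 101. In 20 simulated sets with 1 list raised 2-fold, camera called that list in all 20 and called other lists in 2 of 360 tests (0.556%). The exact test of the list means gave an unadjusted p under the threshold for 7.78% of the unchanged lists. Simulated genes were drawn independently of each other, so the rates for lists do not cover correlation between genes. In the data the estimated correlation was 0.145 for the homeostatic list and 0.479 for the astrocyte list.

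Alternatives fixed in advance were size factors of the DESeq2 type (RLE), upper-quartile factors, no filter on low counts, a filter of 2 CPM in 6 libraries, voomWithQualityWeights and voom of limma, DESeq2 1.42.0 (Wald test), 1 surrogate variable (sva 3.50.0), limma-trend on log2 of the deposited RPKM plus 1 or plus 0.1, camera with an estimated correlation, fry, z-scores or a prior count of 0.5 for the list means, and omission of each library in turn. Alternatives chosen after seeing the data were thinning all libraries to the smallest total, omission of the least correlated library of each group together, nuclear protein-coding genes only, library totals without TMM factors, and lists without genes shared with the disease-associated list. GC content came from GENCODE vM21 gene models. Figures were drawn with Python 3.11.15.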

Results

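RNA was measured in Cd11b-positive cells sorted from mouse brain, a gate that collects microglia and can also hold other macrophages, monocytes and granulocytes. The mice were males of 6 months of age. A group of 6 libraries came from mice carrying a human tau transgene with the P301S mutation, which is known from inherited frontotemporal dementia (P301S), and 6 came from littermates without the transgene (NonTg). The comparison asks how brain myeloid cells differ between these genotypes. Each library has its own sample identifier in the labels, but no label ties a library to a single animal, a litter, a batch or a pair, so p-values measure the spread between these samples. The numbers of these identifiers run on within a genotype, while the order of the deposited records mixes the genotypes, and the labels used here give no order of handling.

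Total counts per library ranged from 1196069 to 4145069, with a median of 2488085. The P301S libraries averaged 2923600 ± 809100 counts (SD, n = 6) and the NonTg libraries 2045900 ± 825100 (SD, n = 6), with overlapping ranges (exact two-sided permutation p = 0.0952, adjusted p = 0.122 over 9 library measures). Mitochondrial genes took 25.0% ± 6.91 of the counts in P301S and 15.5% ± 3.36 in NonTg, with overlapping ranges (SD, n = 6 each, exact permutation adjusted p = 0.0351). Malat1, an abundant nuclear RNA, took 9.51% ± 1.04 in P301S and 14.7% ± 2.39 in NonTg, without overlap (exact permutation adjusted p = 0.00974). The 10 most abundant genes of each library together took 34.6% ± 6.54 in P301S and 30.6% ± 4.34 in NonTg (exact permutation adjusted p = 0.229). Gene numbers without a symbol took 1.79% ± 0.193 in P301S and 2.65% ± 0.372 in NonTg (exact permutation adjusted p = 0.00974). The first principal component of log2 CPM held 20.1% of the variance and placed all 6 NonTg libraries on one side of zero and all 6 P301S libraries on the other.

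**Figure D1:**
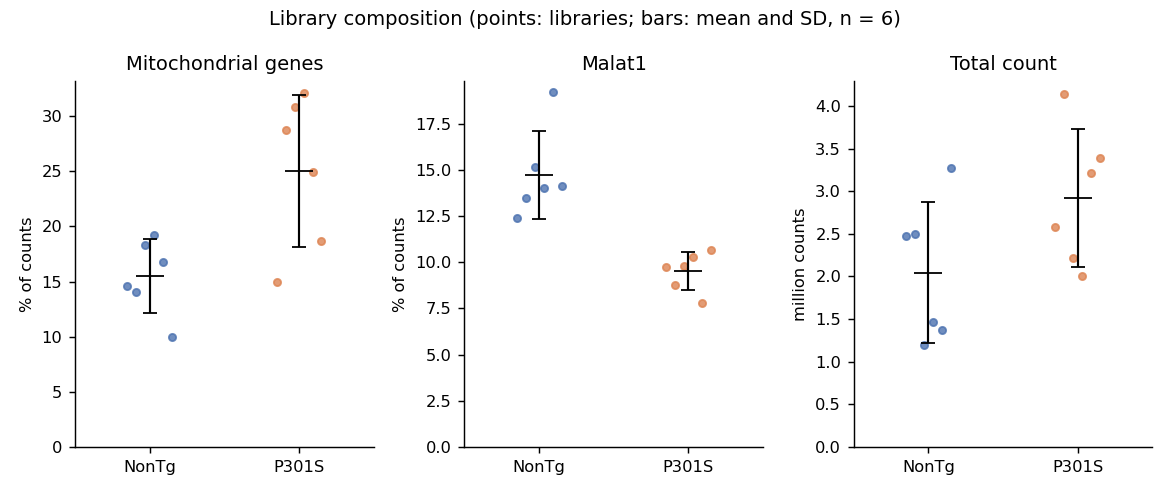
Share of counts from mitochondrial genes (left) and from Malat1 (middle), in percent, and total count (right), for the 6 NonTg and 6 P301S libraries. Points are libraries and bars are the mean and SD. The Malat1 share averaged 14.7% in NonTg and 9.51% in P301S.

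Across all genes, Spp1, which encodes the secreted protein osteopontin, had the smallest p and rose from 0.804 ± 0.550 to 274.6 ± 92.2 CPM (SD, n = 6 each). Cst7, encoding the cysteine protease inhibitor cystatin F, rose from 0.375 ± 0.346 to 58.1 ± 20.6 CPM. Apoe (Entrez 11816, chromosome 7, 19696244 to 19701310 of GRCm38), encoding the lipid carrier apolipoprotein E, rose from 28.7 ± 15.1 to 1267 ± 367 CPM, a log2 fold change of 5.47 ± 0.30 (SE). The same direction was seen for Gpnmb, a transmembrane glycoprotein gene (log2 fold change 5.47 ± 0.64), for the Src-family kinase gene Fgr (5.21 ± 0.59) and for the prostaglandin E2 receptor gene Ptger4 (5.74 ± 0.84). Of 10022 genes tested, 238 rose and 150 fell in P301S at an adjusted p under 0.05 with edgeR's quasi-likelihood test. The P301S libraries lay wholly above the NonTg libraries for 224 genes and wholly below for 105, together 3.28% of genes, where chance gives 0.216%. With no filter on low counts 1063 genes passed, of which 38.7% rose, against 61.3% with the filter, and DESeq2 called 742.

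By log2 fold change, the 10 largest increases also held Rai14 (log2 fold change 5.02 ± 0.44), the kinase gene Fam20c (5.23 ± 0.86), Rab7b, a small GTPase gene of the late endosome (4.92 ± 0.73), and Lox, encoding the collagen cross-linking enzyme lysyl oxidase. Lox had 1 count in all NonTg libraries together and 342 in P301S, a ratio of 249 with a 95% interval of 44.4 to 9860 that covers counting error only (adjusted p = 1.32e-04). Among the 10 largest decreases were the semaphorin gene Sema4b (25.6 ± 11.2 to 1.63 ± 0.837 CPM, log2 fold change -3.96 ± 0.67) and the orphan receptor gene Gpr165 (-3.58 ± 0.91). Asb15 (-4.62 ± 1.13), Cntnap5a (-3.74 ± 0.97) and Vopp1 (-3.43 ± 0.84) also fell, with adjusted p-values of 0.0329, 0.0305 and 0.0160. Gm5415 (-3.45 ± 0.78), the non-coding genes Gm36774 (-3.63 ± 0.77) and Gm35247 (-3.44 ± 0.50), and Entrez genes 102642326 (-4.68 ± 0.87) and 102637867 (-3.74 ± 0.88), which had no symbol in the annotation used, completed the set. Omitting NonTg 5 ended the calls of Vopp1 (log2 fold change -2.53, adjusted p = 0.128), 102637867 (-3.00, 0.0764) and Gm5415 (0.0563), and those of Asb15, Cntnap5a and Gpr165, the last without counts in NonTg 3, were lost on omission of any of 4, 7 and 4 libraries. With voom, Vopp1, Cntnap5a, Asb15, 102637867 and Gm5415 were not called (adjusted p = 0.139, 0.559, 0.0954, 0.0948 and 0.0507), and on the deposited RPKM plus 1 the log2 fold changes of Lox and Fam20c were 0.77 and 1.30, both still called. Protein-coding genes gave 223 of the increases and 115 of the decreases (8867 tested), while non-coding genes gave 8 increases and 20 decreases (614 tested). Genes without a symbol gave 7 and 15 (541 tested). The share of counts from non-coding genes and pseudogenes other than Malat1 was also lower in P301S. It was 1.99% ± 0.225, against 2.78% ± 0.443 in NonTg (exact permutation adjusted p = 0.0146).

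Mouse Mapt, the endogenous tau gene on chromosome 11 from 104229409 to 104332090 of GRCm38, was near the lower end of detection in both groups. It measured 6.31 ± 3.33 CPM in NonTg and 5.21 ± 5.22 in P301S, a log2 fold change of -0.30 ± 0.78 that did not pass (adjusted p = 0.915). Prnp, the prion protein gene, measured 10.0 ± 8.96 and 8.22 ± 5.83 CPM (log2 fold change -0.26 ± 0.74, adjusted p = 0.924), with P301S 1 at 19.9 CPM and the other 5 P301S libraries at 6.63 or less, and its sign turned under 4 of the other settings. Reads of the human transgene were not analysed here, so Mapt does not check the genotype labels. Itgam, encoding the Cd11b protein used for sorting (chromosome 7, 128062640 to 128118491), fell from 1869 ± 286 to 1250 ± 135 CPM, below the NonTg range in 6 of 6 P301S libraries. Its log2 fold change was -0.58 ± 0.15 (adjusted p = 0.0264), and the call was lost on omission of any of 7 of the 12 libraries and with 2 other filters on low counts (highest adjusted p 0.0907).

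Genes of the disease-associated microglial state, a program described for microglia near amyloid and in other brain disease, were higher in P301S as a group. Of 35 list members tested, 25 rose and none fell, and the median log2 fold change was 2.35. Itgax, encoding the integrin Cd11c (chromosome 7, 128129526 to 128150657), rose from 11.4 ± 8.37 to 332 ± 63.5 CPM (log2 fold change 4.88 ± 0.41). Lgals3bp, encoding a secreted galectin-binding protein, rose by 3.30 ± 0.29, and Clec7a, encoding the pattern receptor dectin-1, by 4.31 ± 0.84 (4.93 ± 9.93 to 107 ± 34.7 CPM). In Clec7a the library NonTg 1 stood apart at a log2 CPM of 4.70, and without it the log2 fold change was 6.65. Trem2, the lipid-sensing receptor gene of this program, measured 125 ± 34.2 CPM in NonTg and 196 ± 70.3 in P301S, a log2 fold change of 0.65 ± 0.27 that did not pass (adjusted p = 0.192). Adjusted over the list alone, 32 members rose and none fell, and 0 were lower at an unadjusted p under 0.05 or with DESeq2. The camera test gave an adjusted p of 8.02e-45, and 9.89e-05 with an estimated correlation. The mean log2 CPM of the list was 6.90 ± 0.192 in P301S and 4.03 ± 0.311 in NonTg, higher in 6 of 6 libraries (exact permutation p = 0.00217, the smallest that 924 assignments allow). The list was drawn from general knowledge of microglial states, not from these libraries. The P301S group also had the larger mean mitochondrial share (25.0% against 15.5%) and the smaller Malat1 share (9.51% against 14.7%).

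**Figure D2:**
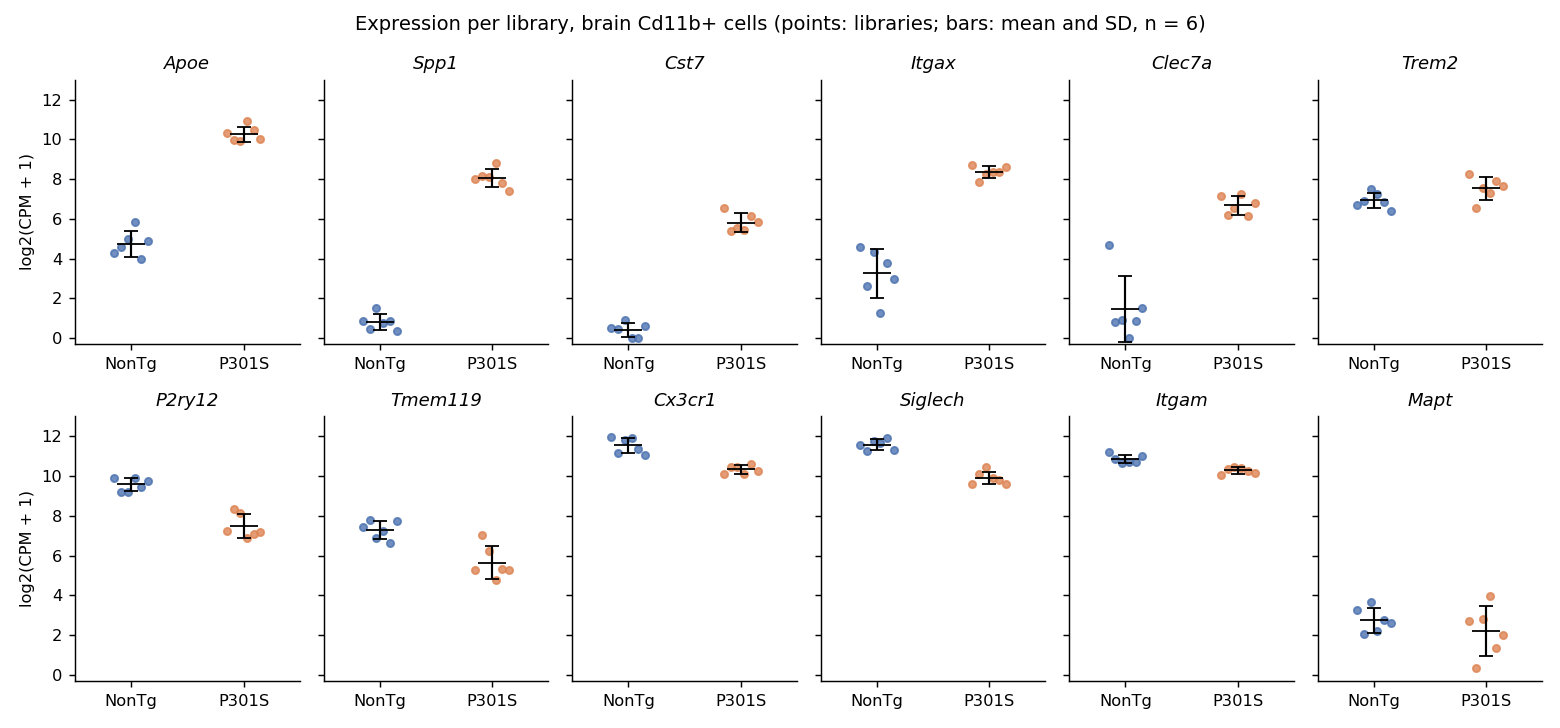
Expression of 12 genes in each library as log2(CPM + 1), for the 6 NonTg and 6 P301S libraries. Points are libraries and bars are the mean and SD. Apoe, Spp1, Cst7 and Itgax were higher in all 6 P301S libraries than in any NonTg library, P2ry12, Cx3cr1, Siglech and Itgam were lower in all 6, and Trem2 and Mapt overlapped.

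Markers of homeostatic microglia were lower in P301S. P2ry12, encoding the purinergic receptor that guides microglial processes (chromosome 3, 59216271 to 59262985), fell from 782 ± 174 to 193 ± 88.5 CPM (log2 fold change -2.02 ± 0.25). Siglech, a sialic acid-binding lectin gene, fell from 3105 ± 554 to 982 ± 232 CPM (-1.66 ± 0.17), and Cx3cr1, the fractalkine receptor gene, fell from 3077 ± 822 to 1300 ± 185 CPM (-1.24 ± 0.17). Tmem119 fell from 162 ± 50.5 to 57.2 ± 38.4 CPM (-1.50 ± 0.34), and Ecscr had a log2 fold change of -2.76 ± 0.37. Of 28 members tested, 13 fell, 1 rose (Egr1, an immediate early transcription factor gene) and 14 did not pass. Adjusted over the list alone, 15 fell and 1 rose. The list median was -0.65 (camera adjusted p = 1.20e-09, and 0.0305 with an estimated correlation), and the mean log2 CPM of the list was lower in 6 of 6 P301S libraries (exact permutation p = 0.00217). Members that did not pass included Csf1r (-0.33, adjusted p = 0.309) and Sall1 (-0.40, 0.337), so the decrease did not cover the whole list.

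Genes of the type I interferon response were higher in P301S. Slfn5 (log2 fold change 2.09 ± 0.44), Ifi204 (1.89 ± 0.35) and Trim30a (1.06 ± 0.22), all interferon-induced, rose. Of 34 members tested 7 rose and none fell, and 18 rose when adjusted over the list alone, with a median of 1.18. Camera gave an adjusted p of 1.20e-13 (0.0108 with an estimated correlation), and the list mean was higher in 6 of 6 P301S libraries (exact permutation p = 0.00217). The number of members past the threshold ranged from 4 to 15 over the settings tried. Ifi204 belongs to a cluster of similar genes, so its count is less certain.

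Antigen presentation genes of both classes were higher. In class I, B2m, the shared light chain gene, rose from 220 ± 93.1 to 628 ± 150 CPM (log2 fold change 1.51 ± 0.25), H2-D1 by 2.45 ± 0.36, H2-K1 by 1.49 ± 0.28 and the class I transactivator gene Nlrc5 by 2.77 ± 0.54. These were the 4 of 13 tested members that rose, none fell, and 5 rose when adjusted over the list alone (median 0.93, camera adjusted p = 1.33e-04, and 0.00963 with an estimated correlation). In class II, the invariant chain gene Cd74 rose from 28.9 ± 21.3 to 149 ± 56.4 CPM (2.34 ± 0.41) and H2-Ab1 by 1.98 ± 0.44, and the other 6 tested members did not pass. Adjusted over the list alone 3 of the 8 rose (median 0.95, camera adjusted p = 0.00144, and 0.0389 with an estimated correlation). The H2 genes share sequence with each other, and their values depend on how unique reads were assigned.

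Lysosomal and lipid-handling genes were higher. Ctsd and Ctsb, encoding the lysosomal proteases cathepsin D and B, rose from 1198 ± 288 to 3518 ± 1049 CPM (log2 fold change 1.55 ± 0.19) and from 227 ± 82.1 to 949 ± 158 CPM (2.06 ± 0.22). Ctsz rose by 1.69 ± 0.29, and Grn, the progranulin gene, by 1.24 ± 0.21. Of 39 lysosomal genes 12 rose and none fell, and adjusted over the list alone 21 rose and 1 (Lgmn) fell (median 0.76, camera adjusted p = 5.20e-11, and 0.00963 with an estimated correlation). Of 19 lipid-handling genes 4 rose and none fell: Apoe, the cholesterol esterification gene Soat1 (1.90 ± 0.33), the acetyl-CoA carboxylase gene Acaca (2.31 ± 0.47) and the cholesterol transfer gene Npc2 (1.15 ± 0.30), whose call was lost on omission of any of 4 libraries. Adjusted over the list alone 9 rose (median 0.83, camera adjusted p = 3.32e-09, and 0.00290 with an estimated correlation). With the 6 lysosomal and 3 lipid genes that were also on the disease-associated list left out, a setting chosen after seeing the data, camera gave adjusted p-values of 9.11e-07 and 2.72e-05. Cholesterol synthesis genes showed no such shift, with 0 of 11 past the edgeR threshold, also when adjusted over the list alone, 2 at an unadjusted p under 0.05 and 0 with DESeq2 (median 0.34, camera adjusted p = 0.836, and 0.399 for the list mean by exact permutation).

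Glycolysis genes were moderately higher, and so were complement genes, except by camera with an estimated correlation. C3, the central complement component, rose from 1.43 ± 2.60 to 30.0 ± 21.1 CPM (log2 fold change 4.22 ± 0.82, and 6.07 without NonTg 2), C1qb from 546 ± 171 to 1153 ± 246 CPM (1.08 ± 0.21), and C3ar1 by 1.17 ± 0.28. With Itgax, a complement receptor subunit gene, these made 4 of 13 members that rose, while 1 fell, the receptor subunit gene Itgam. Adjusted over the list alone 5 rose and 1 fell (median 0.42, camera adjusted p = 0.00184), but the adjusted p was 0.0526 with an estimated correlation. The complement list mean gave an exact permutation adjusted p of 0.00520. Among 17 glycolysis genes 3 rose: Hif1a, encoding a hypoxia-inducible transcription factor (1.70 ± 0.28), Aldoa, the aldolase A gene (2.31 ± 0.52), and Pfkfb3, a regulator of glycolytic flux (1.01 ± 0.23). Adjusted over the list alone 5 rose (median 0.56, camera adjusted p = 3.99e-04, and 0.0307 with an estimated correlation). Of 22 nuclear-encoded oxidative phosphorylation genes tested, from a list of 40, 0 passed with edgeR, also when adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 with DESeq2 (median 0.31, camera adjusted p = 0.387).

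Inflammatory cytokine and NF-kB genes did not pass as a group, although 3 of them rose. The chemokine genes Ccl3 (log2 fold change 2.35 ± 0.62, adjusted p = 0.0276) and Ccl2 (2.98 ± 0.83, 0.0395) and the NF-kB regulator gene Nfkbiz (1.22 ± 0.34, 0.0402) were those 3, while the interleukin gene Il1a had a log2 fold change of -0.83 ± 0.27 that did not pass (0.0816). Of 15 members 3 rose and 0 fell with edgeR, with 4 higher and 2 lower when adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 1 lower with DESeq2. The list did not pass (median 0.72, camera adjusted p = 0.0579, 0.287 with an estimated correlation and 0.361 without the 2 members shared with the disease-associated list), though it did in 8 other settings. The calls of Ccl3, Ccl2 and Nfkbiz were lost on omission of any of 4, 9 and 8 of the 12 libraries.

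Immediate early genes that tissue dissociation can induce were also scored. Egr1 rose from 7.95 ± 8.67 to 109 ± 42.3 CPM (log2 fold change 3.72 ± 0.54), Egr2 by 4.63 ± 0.72 and Atf3, a stress-induced transcription factor gene, by 3.46 ± 0.64. The other 13 of 16 members did not pass, and the count adjusted over the list alone was also 3 (median 0.16, camera adjusted p = 0.0428, and 0.0768 with an estimated correlation). Omission of NonTg 1, NonTg 5 or P301S 3 also ended this list's camera call, with adjusted p-values of 0.0690, 0.0776 and 0.0962. The mean log2 CPM of the immediate early list was 4.155 ± 0.177 in P301S and 3.349 ± 0.263 in NonTg, without overlap (exact permutation adjusted p = 0.00520). A difference in dissociation or handling between the genotypes was not tested. In the integrated stress response list Atf3 was the only 1 of 13 members past the threshold, 2 when adjusted over the list alone (median 0.34, camera adjusted p = 0.0143, and 0.117 with an estimated correlation). Its list mean gave an exact permutation adjusted p of 0.0130.

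Ribosomal protein genes were higher in P301S, from a low level. Rpl4 rose from 97.3 ± 18.6 to 181 ± 47.7 CPM (log2 fold change 0.89 ± 0.24, adjusted p = 0.0353) and Rps15 from 3.96 ± 1.41 to 18.8 ± 5.30 CPM (2.22 ± 0.62, 0.0388). These were the 2 of 18 members past the threshold, and 7 rose and 1 (Rpl5) fell when adjusted over the list alone. The list median was 1.10 (camera adjusted p = 5.71e-08, and 0.00963 with an estimated correlation). Omitting any of 6 libraries in turn ended the call of Rpl4, and any of 8 that of Rps15, and with all libraries kept 2 and 5 other settings did so (highest adjusted p 0.0671 and 0.0700). The Malat1 share was lower in the same libraries (9.51% against 14.7%).

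The list mean of mouse orthologs of Alzheimer disease risk genes was higher in P301S, but the list did not pass against other genes. Apoe and Grn rose, and Cd33, encoding a sialic acid-binding receptor, fell from 854 ± 149 to 427 ± 95 CPM (adjusted p = 0.00112). Of 26 members 2 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone. The fold change was positive for 13 of the 26, called or not. Camera gave an adjusted p of 0.278 (median 0.02), while the list mean differed by 0.37 on the log2 scale (exact permutation adjusted p = 0.0160), and fry, which does not compare the list with other genes, gave 0.0108. Summed CPM went from 4466 ± 254 to 5393 ± 135 (exact permutation adjusted p = 0.00714), while Apoe alone rose by 1238 CPM. Without Apoe and Trem2, which are also on the disease-associated list, the median was -0.12 and the camera adjusted p 0.819. That setting was chosen after seeing the data. Of 30 proliferation genes only 9 had enough counts to be tested. These did not pass either, with 0 of 9 called by edgeR, also when adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 by DESeq2 (median 0.07, camera adjusted p = 0.594).

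**Figure D3:**
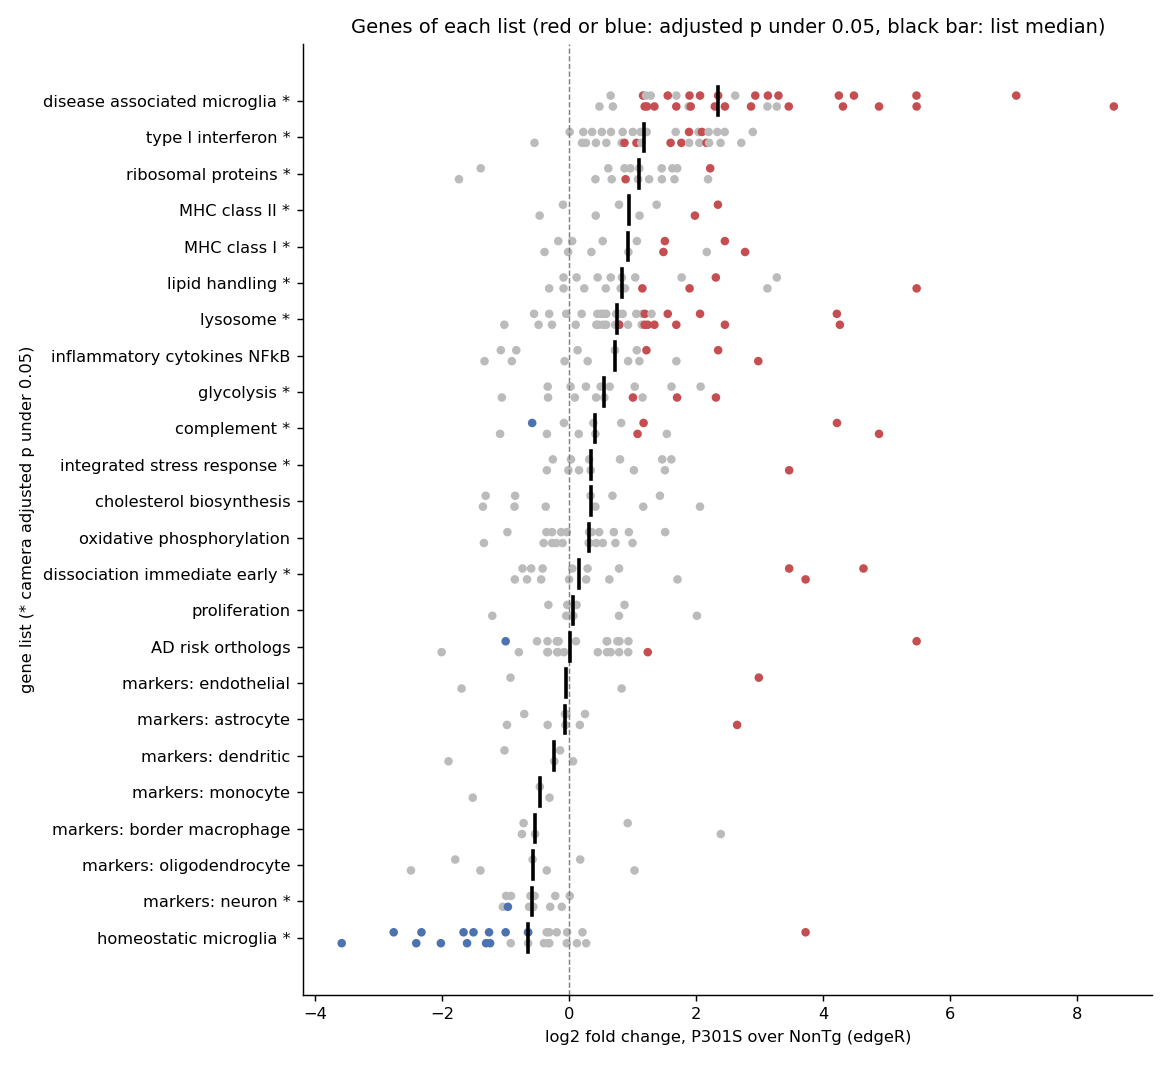
Log2 fold change, P301S over NonTg, of every tested gene in the 24 lists with at least 3 tested genes. Red and blue points are genes higher or lower at an adjusted p under 0.05, grey points did not pass, black bars are list medians and asterisks mark lists past the camera threshold. The disease-associated list had the highest median, 2.35, and the homeostatic list the lowest, -0.65.

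Few markers of other brain and blood cells passed. Border macrophage markers, such as Mrc1 (20.5 ± 18.3 CPM in NonTg, 12.1 ± 7.24 in P301S) and Siglec1 (4.21 ± 5.85 and 21.5 ± 9.18), gave 0 of 5 called by edgeR and 1, Siglec1, higher when adjusted over the list alone. Their median was -0.53 but their mean 0.26, and camera pointed up with an adjusted p of 0.728. Monocyte markers had 0 of 3 called, with a median of -0.46 and a mean of -0.76, while camera, which uses another scale, pointed up (adjusted p = 0.836). Dendritic cell markers gave 0 of 5 (median -0.23, adjusted p = 0.333) and oligodendrocyte markers 0 of 7 (median -0.57, adjusted p = 0.184). At an unadjusted p under 0.05 stood 1 border macrophage marker (Siglec1), 0 monocyte, 1 dendritic cell and 3 oligodendrocyte markers, and DESeq2 called 0 of any of these 4 lists. Among endothelial markers Flt1, a vascular growth factor receptor gene, rose (log2 fold change 2.99 ± 0.64) and the other 3 did not pass, with a median of -0.05, a mean of 0.30 and a camera adjusted p of 0.417 (up). Among astrocyte markers Gfap, an intermediate filament gene, rose from 3.14 ± 2.23 to 19.8 ± 4.37 CPM (2.65 ± 0.67, adjusted p = 0.0199), while the other 8 did not pass. The astrocyte median was -0.06, its mean 0.10 and its camera adjusted p 0.836 (up).

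Neuronal markers were lower in P301S by camera with the preset correlation, but did not pass with an estimated one. Meg3, a non-coding RNA abundant in neurons, fell from 936 ± 402 to 480 ± 95.3 CPM (log2 fold change -0.96 ± 0.23, adjusted p = 0.0115), with the call lost without NonTg 6 (0.0569) and on either form of the deposited RPKM (highest 0.0663), and the other 11 members did not pass, also when adjusted over the list alone. Camera called the list (median -0.58, adjusted p = 0.00872), but the adjusted p was 0.154 with an estimated correlation and 0.0693 for the list mean by exact permutation. Among B cell markers Bank1, a signalling scaffold gene, fell from 188 ± 73.7 to 26.9 ± 15.4 CPM (-2.81 ± 0.41), and Cd22, which is also on the disease-associated list, rose (2.93 ± 0.62). They were the only B cell markers tested.

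For lists with fewer than 3 tested genes, CPM were summed over all members. B cell markers summed to 212 ± 65.0 CPM in NonTg and 83.5 ± 31.4 in P301S (SD, n = 6 each, exact permutation adjusted p = 0.00714), a difference carried by Bank1. Neutrophil markers summed to 649 ± 123 and 853 ± 131 CPM (exact permutation adjusted p = 0.0510), a difference carried by Csf3r (601 ± 121 and 837 ± 130, uncalled), with 47.1 and 15.6 for the other members, and T cell markers to 44.2 ± 21.7 and 33.3 ± 12.1 (0.429). Natural killer cell markers summed to 6.52 and 7.06 CPM, erythroid markers to 7.80 and 2.61, mural cell markers to 32.2 and 16.9, and choroid plexus and ependymal markers to 38.2 and 45.4. Fibroblast markers summed to 87.6 and 73.1 CPM and oligodendrocyte precursor markers to 134 and 93.0. The exact permutation adjusted p-values of these were 0.942, 0.122, 0.308, 0.738, 0.491 and 0.127 in the order given.

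Of the 24 lists tested, 11 passed as higher and 2 as lower in P301S. With an estimated correlation between genes 9 passed, the complement, integrated stress response, immediate early and neuron lists being lost. The exact permutation test of the list means also called 13 lists, but not the same 13. It called the Alzheimer risk list (adjusted p = 0.0160) and not the neuron list (0.0693). The complement, integrated stress response and immediate early lists were among its calls.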

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

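The tests of library depth, of border macrophages and monocytes, of other immune cells, and of astrocyte RNA were chosen only after the results they bear on were seen. The others were fixed earlier.

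Single libraries stood apart from the rest of their group in 6 of 124 groups of values tested with Dixon's criterion, where chance gives about 1 in 20 groups (6.2 here). Clec7a, the dectin-1 gene, had a log2 CPM of 4.699 in NonTg 1, against -0.303 to 1.427 in the other NonTg libraries. Prnp was at 4.374 in P301S 1 and between 2.207 and 2.895 in the other P301S libraries. Gpr165 was at -0.303, the value of no counts, in NonTg 3 and between 4.557 and 5.039 in the other NonTg libraries. The non-coding gene Gm36774 was at 2.465 in NonTg 2, against 4.594 to 5.799. Lox was at 0.786 in NonTg 3, the only NonTg library with a count, against -0.303 in the others. The mean log2 CPM of oligodendrocyte markers was 3.785 in NonTg 4 and between 4.618 and 4.879 in the other NonTg libraries.

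The rise of the disease-associated list (Apoe, Spp1, Cst7, Itgax and others) was set against 4 technical explanations. With all libraries thinned to the smallest total, which left 7848 genes tested, the list median was 2.394, against 2.347 before. The rise was thus present at equal depth. Thinning keeps the expected share of each gene, however, so it could hardly have removed the rise, and the 2 medians need not cover the same members. The highest median of 1000 random lists matched on gene length and expression was 0.476, which argues against a length trend. Border macrophages or monocytes in the sort would bring their own markers, but the summed CPM of both marker lists went from 338 to 246. The upper end of the 95% bootstrap interval of their rise was 19.04 CPM, against a rise of 1238 CPM for Apoe. Without NonTg 2, at 625.1 CPM, the sum went from 280 to 246 with an upper end of 42.97. Without Stab1 and Fn1, which carried the decrease, it went from 90.1 to 91.7 with an upper end of 36.46. Siglec1 alone went from 4.21 to 21.5 CPM. The marker sums thus showed no clear rise. How much Apoe RNA such cells hold per marker RNA was not measured. Other members rose by far fewer CPM than Apoe (Cst7 from 0.375 to 58.1). The comparison therefore cannot exclude these cells as a part of the rise. For markers of T, natural killer and dendritic cells the highest such upper end was 9.21 CPM, so their sums showed no large rise, with the same limit. For neutrophils and B cells the outcome depended on single genes. Neutrophil markers without Csf3r went from 47.1 to 15.6 CPM, but with it the upper end was 338.29 CPM. Csf3r alone, uncalled, went from 601 to 837 CPM. The B cell decrease was carried by Bank1 (188 to 26.9 CPM), while Cd22 went from 6.74 to 51.4 CPM. The test cannot decide for either of these cell types. A changed state of microglia in P301S mice was not tested and stays open.

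The rise of the ribosomal protein list (Rpl4, Rps15 and others, median 1.10) lay at percentile 100 of 1000 random lists matched on expression and gene length, and also at percentile 100 of those matched on expression and GC content. Both trends are therefore argued against as the whole cause. A smaller share of nuclear RNA in P301S libraries, for which the lower Malat1 share gave the idea, predicts lower values of other nuclear RNAs. Meg3 was left out of this test in advance along with Malat1, and was itself lower (log2 fold change -0.96, edgeR adjusted p = 0.0115). The 6 others tested (Neat1, Kcnq1ot1 and 4 more) had a median log2 fold change of -0.099. That lay inside the range of random lists (-0.634 to 0.599), so the nuclear RNA explanation may hold or not. No biological explanation beyond genotype was tested.

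Gfap, the astrocyte filament gene, rose by 2.65 ± 0.67 on the log2 scale. If more astrocyte RNA had come through the sort, the other astrocyte markers would rise alike, but the 8 others had a median of -0.061. That median plus 2 standard errors (0.295) lay below the lower bound of Gfap (1.309). The standard error of the median came from resampling the 8 genes, so it leaves out the spread between libraries. Between libraries the mean log2 CPM of the astrocyte list had an SD of 0.849 in NonTg and 0.707 in P301S. Slc1a2, the glutamate transporter gene and the most abundant of them, measured 308 CPM in NonTg and 299 in P301S. Vim, a filament gene on no astrocyte list here and looked up after its value was seen, had a log2 fold change of 2.21 ± 0.68 (edgeR adjusted p = 0.0664). A changed state of the same amount of astrocyte RNA was not tested and stays open.

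Chance division of the libraries was tested with 100 of the 462 splits into equal groups. The real split called 388 genes, the highest of the others 14, and 1 of the 100, the real one, gave as many, so chance alone is unlikely for the gene count. For lists the real split called 13 and 2 of the 100 gave as many, the real one included, the highest of the others also being 13. That other split kept 5 P301S libraries on one side, so it largely followed genotype. A share of 2 in 100 makes chance unlikely for the number of lists but does not exclude it. It says nothing about any single list.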

How the results depend on the processing

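The settings that thinned the libraries, left out the least correlated library of each group, kept nuclear protein-coding genes, used totals without TMM factors or left out shared list genes were chosen after seeing the data. Of 93 genes followed through the settings, 73 kept direction and side of the threshold in every setting run, 16 lost their call in some, 3 gained one (Siglec1, Il1a, Vim) and 1 (Prnp) turned. A gene whose adjusted p was missing with DESeq2 was counted as unchanged in that setting. No scaling moved the median of all genes by over 0.1. The disease-associated, homeostatic, interferon, lysosomal and class I lists passed in every setting run. Where a value moved, the cause was not tested, except that fits without a library hold fewer samples.

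The 388 calls became 1063 with no filter on low counts (411 higher, 652 lower), where 29308 genes were tested, and 742 with DESeq2 (405 higher, 337 lower, 250 adjusted p-values not given). In all other settings the count was between 273 and 507. Omitting each library in turn gave 273 to 386 calls, 182 to 242 higher and 91 to 169 lower, with 91 lower without P301S 1 and 96 without P301S 6. Interferon genes past the threshold numbered 11 with no filter, 12 with DESeq2, 15 with voom and with voomWithQualityWeights, and 14 with either RPKM pseudocount, against 7. They were 4 to 9 on omitting a library, with 4 without NonTg 4, P301S 3, P301S 5 or P301S 6. Lists called numbered 12 to 14 on omitting a library.

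Prnp, uncalled throughout, had log2 fold changes of 0.4472 (voomWithQualityWeights), 0.4591 (voom) and 0.0179 (RPKM plus 0.1), and of -0.74 to 0.22 on omitting a library, turning without NonTg 4. Uncalled lists also turned direction, with these adjusted p-values. Monocyte: 0.6843 (no filter), 0.9498 (thinned), 0.9404 (least correlated out) and 0.3217 to 0.9969 on omission, turning without NonTg 3, NonTg 4 or P301S 3. Astrocyte: 0.8752 (2 CPM filter) and 0.3915 to 0.9969, turning without NonTg 2, P301S 1, P301S 2 or P301S 3. Cholesterol synthesis: 0.9388 (surrogate variable), 0.6242 (thinned) and 0.6899 to 0.9885, turning without NonTg 3. Border macrophage: 0.3712 to 0.9237, turning without NonTg 4.

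The NF-kB list passed with no filter (0.00102), the 2 CPM filter (0.0364), voomWithQualityWeights (0.0336), the least correlated libraries out (0.0362), protein-coding genes (0.0327), and without NonTg 1 (0.0231), NonTg 3 (0.0300) or P301S 2 (0.0252). The immediate early list was also lost with a surrogate variable (0.0512) and protein-coding genes (0.0508). The oligodendrocyte list passed as lower with the least correlated libraries out (0.0358), and the Alzheimer list as higher with no filter (0.0201).

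Calls lost on omitting 1 library, with the highest adjusted p, were Ccl2 (0.125, all but NonTg 1, P301S 4 and P301S 5), Nfkbiz (0.137, all but NonTg 1, NonTg 2, P301S 2 and P301S 4), Rps15 (0.0976, all but NonTg 2, NonTg 4, P301S 2 and P301S 4), Itgam (0.0855, NonTg 1, 2 and 6, P301S 1, 3, 5 and 6), Cntnap5a (0.114, NonTg 3 and 5, P301S 1, 2, 3, 5 and 6), Rpl4 (0.0862, NonTg 3, 5 and 6, P301S 1, 4 and 5), Asb15 (0.0762, P301S 1, 3, 5 and 6), Ccl3 (0.0856, NonTg 6, P301S 1, 2 and 5), Gpr165 (0.0633, NonTg 4, P301S 1, 2 and 5), Malat1 (0.0769, NonTg 5, P301S 1, 5 and 6), Npc2 (0.0674, NonTg 5, P301S 2, 5 and 6), Vopp1 (0.128, NonTg 5 and P301S 6), 102637867 (0.0764) and Gm5415 (0.0563, both NonTg 5), and Meg3 (0.0569, NonTg 6). Folds of called genes moved by over 1.5 times without NonTg 1 (log2 Clec7a 6.65, Ccl2 4.57, Fgr 6.34, Ptger4 6.98, Egr1 4.48), NonTg 2 (C3 6.07), NonTg 3 (Lox 8.54, Cntnap5a -2.80), NonTg 4 (Fam20c 6.82, Rab7b 5.72), NonTg 5 (Vopp1 -2.53, 102637867 -3.00), NonTg 6 (Egr2 5.89), P301S 3 (102642326 -5.41), P301S 4 (Gpnmb 4.88, Asb15 -5.47, 102637867 -4.72), P301S 5 (Gm36774 -4.50) and P301S 6 (Gpr165 -4.39). Of 82 called genes, 32 had folds smaller by over 1.5 times on RPKM plus 1 (log2 Lox 0.77, Fam20c 1.30, Ptger4 1.54, C3 1.05, Gpnmb 2.03, Fgr 2.41, Sema4b -1.08, Gfap 0.76, still called) and 17 on RPKM plus 0.1 (Lox 2.83). Folds of 4 were smaller by as much with a surrogate variable, 4 with voom and 3 with quality weights (Cntnap5a -2.10, -1.77, -2.13, Vopp1 -2.64, -2.54, -2.60). Larger by as much were 2 on RPKM plus 0.1, 3 with voom and 5 with quality weights (Clec7a 5.20, 5.71, 5.98). Of the 82, calls were lost for 9 with voom (Vopp1, Cntnap5a, Asb15, 102637867, Gm5415, COX1, Malat1, Nfkbiz, Rps15), 7 with quality weights, 7 and 5 on RPKM plus 1 and 0.1, 5 with a surrogate variable, 4 without TMM factors (Nfkbiz, Npc2, Rpl4, Rps15), 2 with no filter (Itgam, Rps15), 1 with the 2 CPM filter (Itgam) and 1 thinned (Rps15). Depth limits genes of a few CPM most, where NonTg levels of Lox, Cst7 and Spp1 rest on 1, 5 and 8 counts.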

Other observations

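Apart from Itgam, Itgax, Siglec1, Mrc1 and Stab1, the genes described here are on none of the fixed lists and were chosen after their values were seen, so no theme is tested with them. Lilrb4a, encoding an inhibitory immunoglobulin-like receptor, rose in P301S from 25.8 ± 13.1 to 249 ± 40.0 CPM (SD, n = 6 each, log2 fold change 3.24 ± 0.33, edgeR adjusted p = 1.51e-07). Lag3, a checkpoint receptor gene, rose from 16.9 ± 14.7 to 106 ± 29.2 CPM (2.60 ± 0.47), and Cd274, encoding the checkpoint ligand PD-L1, from 47.4 ± 26.6 to 173 ± 49.4 CPM (1.87 ± 0.34). Cd83, an activation marker gene, rose from 29.2 ± 6.92 to 144 ± 47.2 CPM (2.31 ± 0.31). Myo5a, encoding an organelle-transporting myosin, had the smallest p of any gene off the lists and rose from 155 ± 35.8 to 1151 ± 314 CPM (2.89 ± 0.21). Each of these 5 genes was above the NonTg range in 6 of 6 P301S libraries and passed in every setting run.

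The elongation factor genes Eef2 (112 ± 28.0 to 428 ± 186 CPM, log2 fold change 1.92 ± 0.27) and Eef1a1 (104 ± 31.4 to 291 ± 76.4 CPM, 1.48 ± 0.24) and the ferritin heavy chain gene Fth1 (81.8 ± 41.4 to 296 ± 85.5 CPM, 1.85 ± 0.29) rose and were above the NonTg range in 6 of 6 libraries. Of mitochondrial transcripts, the ribosomal RNA gene mt-Rnr2 rose by 1.35 ± 0.21 and COX1, a cytochrome oxidase subunit gene, by 1.12 ± 0.19, although COX1 lost its call with voom and voomWithQualityWeights (highest adjusted p 0.146). Among decreases, Csmd3, a large transmembrane protein gene, fell from 1380 ± 191 to 468 ± 54.2 CPM (-1.56 ± 0.16), Ivns1abp from 3024 ± 372 to 1107 ± 271 CPM (-1.45 ± 0.17), and the macrophage transcription factor gene Maf from 441 ± 105 to 170 ± 41.6 CPM (-1.38 ± 0.22). Malat1 fell by 0.59 on the log2 scale (SE 0.15, adjusted p = 0.0162), a call lost in 9 of 25 other settings.

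Itgam and Itgax, which encode related integrin chains and lie next to each other on chromosome 7, moved in opposite directions, by -0.58 ± 0.15 and 4.88 ± 0.41. Siglec1, a marker of border macrophages and of interferon exposure, measured 4.21 ± 5.85 CPM in NonTg and 21.5 ± 9.18 in P301S. It did not pass (adjusted p = 0.126) but passed in 6 of 26 other settings, with adjusted p-values from 0.00853 to 0.266 over all of them, while Mrc1 and Stab1, other border macrophage markers, had log2 fold changes of -0.74 ± 0.63 and -0.53 ± 0.27 and did not pass.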
